A study of Avena sativa/Zea mays addition line with 14 samples.

How the data were processed

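CenH3 ChIP-seq was deposited for 10 libraries of 9 oat-maize addition lines, and RNA-seq for 2 libraries each of neoM3 and OMA3.01, 14 samples in all, from young leaves of greenhouse plants per the labels. RNA was poly(A) RNA per the labels. The ChIP-seq values are deposited as a whole-number count per 10 kb window of the added maize chromosome, not scaled to library size. The RNA-seq values are FPKM per gene of maize chromosome 3, per the file headers, with limits and an estimate status for each gene. In about 84% of the genes above 0, the upper limit equals FPKM plus 2 square roots of FPKM within 1%. TopHat is named in the submitters' processing notes of 10 samples, with no role or version. The aligner of the window counts, the read filter and the genome build are not given in the sources used here, so positions are those of the files. Chromosomes other than the 8 covered, reads from oat and the raw reads were not used here.

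The following choices were made before the data were examined: the domain rule, the planned tests and their alternatives, and the rule for naming genes. The background of a library was the mean of the windows outside the highest 5% of the chromosome. A window was enriched where the mean of 5 windows centred on it was at least 5 times background, and enriched runs up to 500 kb apart were merged. The domain was the merged run with the largest sum of reads above background, and its size was its span. Shares of reads have 95% Wilson intervals. The rule was tested on simulated counts with a flat background at the level of each of the 10 libraries. Simulated domains of 3.00 Mb at 15 times background were found with a largest border error of 10 kb. An uneven background, as in some of the real libraries, was not simulated, so this error does not carry over to their borders. Runs outside the domain were named if they spanned at least 50 kb and were among the 5 with the most reads above background over all libraries. The relation of size to chromosome length, taken as the end of the last window, was tested over 8 lines, 1 per chromosome, without neoM3, by permutation over all pairings.

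Also tried for the domains, as fixed beforehand, were 3 and 10 times background, merging up to 100 kb and 1 Mb, no smoothing, a background as the median of the windows with reads, the enriched length in place of the span, and leaving out either OMA8.05 library. Chosen after seeing the data were 3 others: the background of neoM3 from the part with reads, a threshold at 25% of the peak height (the 95th percentile of smoothed counts in the domain), and a background from windows 8 to 20 Mb from the domain. For chromosome 3, bins of 1 Mb outside both domains were read-poor under 0.2 of the library's background. The border of the read-poor part was then placed, after seeing these bins, at the split between 70 and 90 Mb that best separated windows with reads from windows without.

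Of 3837 genes, 13 with a failed estimate in a library were left out, and 2216 with a mean of at least 1 FPKM over the 4 libraries were tested. limma with a mean-variance trend was fitted to log2(FPKM + 1), and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Lists set by position (the neoM3 domain, the OMA3.01 domain, and 5 Mb on either side of the neoM3 domain) were tested with camera at a correlation of 0.01 and with fry, and camera p-values were adjusted over the 3 lists. camera compares a list with the other genes and fry asks whether the list itself moved. The fit was tested on simulated data with the 2216 genes, 200 of them changed: it called 49% of the 2-fold and 76% of the 4-fold changes, all with the right sign, and 9 unchanged genes (6.7% of the calls). Also tried were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, centring on library medians, quantile normalization, the replicate number as a term, leaving out each library, an estimated correlation in camera, and domains at 3 and 10 times background. Chosen after seeing the data were centring on the genes before the neoM3 domain, fits of the genes before the border alone, a mean of at least 50 FPKM, and lists from the neoM3 domain by the background of the part with reads. Where a line kept 1 library, that library was assumed to vary like those of the other line.

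Genes in each line were called detected at a mean of 1 FPKM over its 2 libraries. The 4 RNA-seq libraries had FPKM sums of 859227 and 845825 in neoM3 and 783758 and 782595 in OMA3.01, and 59.9, 57.1, 43.4 and 42.6% of the genes were listed at 0. Read totals of the RNA-seq libraries are not given in the sources used here. Pearson's r of log2 values was 0.944 between the neoM3 replicates, 0.968 between the OMA3.01 replicates, and 0.635 to 0.683 between lines. The named genes were to be the 10 with the largest change in each direction among those past the threshold whose library values did not overlap, the 10 with the highest mean inside the neoM3 domain, and the 5 with the highest mean inside the OMA3.01 domain. Of these, 4 are printed by ID and the others as counts. Lists by words in gene descriptions were planned and not run, since no annotation was analysed here. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 were used.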

Results

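CenH3, the histone H3 variant that marks functional centromeres, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in young leaves of 9 oat-maize addition lines, which are oat plants that each carry 1 added maize chromosome. The lines carried maize chromosome 1 (OMA1.36), 2 (OMA2.51), 3 (OMA3.01 and neoM3), 5 (OMA5.60), 6 (OMA6.34), 8 (OMA8.05), 9 (OMA9.41) and 10 (OMA10.26). OMA8.05 had 2 ChIP-seq libraries and every other line had 1, so replicate error of a CenH3 domain was measured in OMA8.05 alone. The deposited read counts covered the added maize chromosome, and their totals ran from 187226 reads in neoM3 to 1648141 reads in OMA2.51. Poly(A) RNA of young leaves was sequenced in 2 libraries of neoM3 and 2 of OMA3.01, and the values were FPKM of 3837 genes of maize chromosome 3. No input or maize-background library was analysed here, so enrichment was measured against the rest of the same chromosome. Intervals below cover counting error only, apart from those for windows with a gene, which come from 1000 bootstrap resamples of 1 Mb blocks. The labels do not say whether the 2 libraries of a group came from separate plants. The p-values of limma and fry therefore measure the spread between these libraries, which may be technical. Those of camera with a preset correlation compare genes with genes. Permutation tests shuffle lines for domain size and genes for expression, as if these were independent.

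The design asked where the functional centromere of each maize chromosome lay in the oat background. Each library held 1 leading CenH3 domain. On chromosome 1 it ran from 131.54 to 135.81 Mb in OMA1.36 and held 11.6% of the library's reads (95% Wilson interval 11.5 to 11.7%), at 11.0 times background. On chromosome 2 it ran from 90.90 to 95.20 Mb in OMA2.51, with 23.7% of the reads (23.6 to 23.7%) and 19.4 times background. On chromosome 3 the OMA3.01 domain ran from 77.23 to 84.69 Mb, with 26.5% of the reads (26.4 to 26.6%) and 12.4 times background. OMA5.60 had the weakest domain over background, 5.5 times, from 102.16 to 104.85 Mb of chromosome 5, with 5.9% of the reads (5.9 to 6.0%). The chromosome 6 domain of OMA6.34 ran from 42.71 to 50.72 Mb and held 51.5% of the reads (51.4 to 51.7%), at 25.1 times background. On chromosome 9 the OMA9.41 domain ran from 53.05 to 55.19 Mb, with 12.7% of the reads (12.6 to 12.8%) and 11.8 times background. The chromosome 10 domain of OMA10.26 ran from 47.28 to 53.17 Mb and held 57.6% of the reads (57.4 to 57.7%), at 37.9 times background, the highest fold of the 10 libraries. The position of OMA5.60 depended on the threshold. At 10 times background its leading run was a 0.09 Mb stretch at 209.92 Mb, far from the domain.

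In OMA8.05 the domain on chromosome 8 ran from 48.80 to 52.79 Mb in replicate 1 and from 48.80 to 52.78 Mb in replicate 2. The starts differed by 0 kb and the ends by 10 kb, which is 1 window. The domain size was 3.985 ± 0.007 Mb (SD, n = 2), although without smoothing the 2 libraries gave 4.49 and 5.33 Mb, and the share of reads inside it was 21.7% ± 0.37 (SD, n = 2). Across the 17580 windows of the chromosome, which are not independent, Pearson's r between the libraries was 0.981 and Spearman's rho 0.796. The libraries held 287873 and 623291 reads, and their counts differed by more than sampling noise (chi-square 20585 on 15829 degrees of freedom, p = 2.6e-132), so they were kept as 2 libraries.

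The sizes of the CenH3 domains were compared across lines. The domain spanned 5.94 ± 3.85 Mb (SD over 9 lines), from 2.14 Mb in OMA9.41 to 14.74 Mb in neoM3, and 4.84 ± 2.11 Mb over the 8 lines without neoM3. The neoM3 span rests on a background taken over a chromosome that is mostly read-poor in that line. With the background of the part with reads, a setting chosen after seeing the data, the neoM3 domain spanned 3.85 Mb. The mean over 9 lines was then 4.73 ± 2.00 Mb (SD). OMA3.01, OMA6.34 and OMA10.26 had domains of 7.46, 8.01 and 5.89 Mb, and the other lines apart from neoM3 lay between 2.14 and 4.30 Mb. Size showed no detectable relation to chromosome length over the 8 lines (Pearson's r = -0.06, exact permutation p = 0.9; Spearman's rho = 0.02, exact permutation p = 0.98, both two-sided, the only relation tested). Without OMA1.36 and OMA10.26, the lines farthest from the median length, r was 0.15 (exact permutation p = 0.67). The sign of r depended on the setting: over the 8 lines it was 0.65 with the median background (exact permutation p = 0.088), and at 25% of the peak height 0.44 (exact permutation p = 0.27), or 0.84 without the same 2 lines (exact permutation p = 0.025). Lines with an even background and lines with an uneven one numbered 4 each, and no correlation was computed over fewer than 6 lines. The span depended on the threshold. The mean was 11.05 Mb at 3 times background and 3.81 Mb at 10 times background. With the threshold at 25% of the peak height, chosen after seeing the data, it was 3.59 ± 0.86 Mb over 9 lines.

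**Figure D1:**
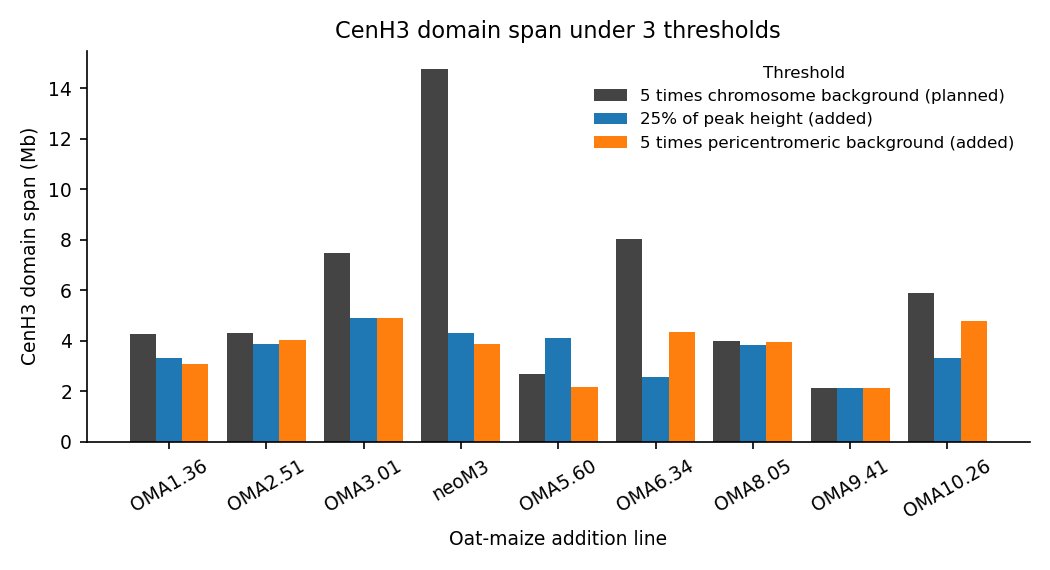
CenH3 domain span in Mb (vertical axis) of each of the 9 addition lines (horizontal axis) under the planned threshold of 5 times chromosome background and 2 thresholds chosen after seeing the data; bars are single libraries except OMA8.05, the mean of 2. The planned spans run from 2.14 Mb in OMA9.41 to 14.74 Mb in neoM3, and those at 25% of the peak height from 2.13 Mb in OMA9.41 to 4.88 Mb in OMA3.01. The planned neoM3 span takes its background over a mostly read-poor chromosome, and was 3.85 Mb with the background of the part with reads.

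Outside the domains, the 5 enriched runs of at least 50 kb with the most reads above background were of different shapes. The run at 51.41 to 52.35 Mb of chromosome 9 in OMA9.41 was 940 kb long at 8.8 times background, its highest window held 2.1% of its 18556 reads, and it lay just before the domain. The others were short piles. On chromosome 2 in OMA2.51, 83035 reads lay at 172.05 to 172.14 Mb, 47.2% of them in 1 window. On chromosome 5 in OMA5.60, 18788 reads lay at 209.92 to 210.03 Mb, 50.7% of them in 1 window. On chromosome 3 a pile at 165.47 to 165.53 Mb held 22401 reads in OMA3.01, 73.9% of them in 1 window, and its counterpart in neoM3, at 165.47 to 165.54 Mb, held 17196 reads, 81.8% of them in 1 window.

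neoM3 and OMA3.01 both carry maize chromosome 3, and were compared to find where their functional centromeres differ. In neoM3, reads thinned out at 80.60 Mb, a border placed after seeing the data, and stayed sparse over the remaining 151.54 Mb of the 232.14 Mb chromosome. Its background fell from 11.8 reads per window before that border to 0.513 after it, or 4.3% of the earlier level, and 62.1% of the windows after it held no read, against 20.8% before. In OMA3.01 the background was 44.3 reads per window before and 38.1 after the border, or 86.1%, with 5.4 and 4.9% of the windows empty. Bins of 1 Mb that were read-poor in neoM3 alone numbered 126, and those read-poor in OMA3.01 alone numbered 2. Before the neoM3 domain the window counts of the 2 lines rose and fell together (Spearman's rho = 0.88 across 6586 windows, which are not independent), whereas after the OMA3.01 domain rho was 0.01.

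CenH3 in neoM3 lay against this border, on the part of the OMA3.01 centromere before it and on its flank. By the planned rule the neoM3 domain ran from 65.86 to 80.60 Mb (14.74 Mb, with 42.6% of its reads, Wilson interval 42.4 to 42.9%), and shared 3.37 Mb with the OMA3.01 domain, or 45.2% of the latter. The shared length ran from 0.06 Mb with merging up to 100 kb to 12.04 Mb at 3 times background. The planned rule takes the background over the whole chromosome, most of which is read-poor in neoM3. With the background of the part with reads, a setting chosen after seeing the data, the domain ran from 76.51 to 80.36 Mb (3.85 Mb) and held 28.0% of the reads (27.8 to 28.2%). With each library divided by its own background before the border, CenH3 at 79 to 80 Mb was 23.34 times background in neoM3 and 14.80 times in OMA3.01. At 78 to 79 Mb it was 9.63 times in neoM3 and 3.34 times in OMA3.01, a ratio of 2.88 (95% counting interval 2.81 to 2.95). At 77 to 78 Mb the ratio was 1.4, and at 76 to 77 Mb it was 0.977 (0.943 to 1.01). The part of the OMA3.01 domain after the border, 80.60 to 84.69 Mb, held 252897 reads in OMA3.01, 13.96 times background, and 541 reads in neoM3, 0.11 times background. Each line had 1 library here, so these differences have no replicate check.

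**Figure D2:**
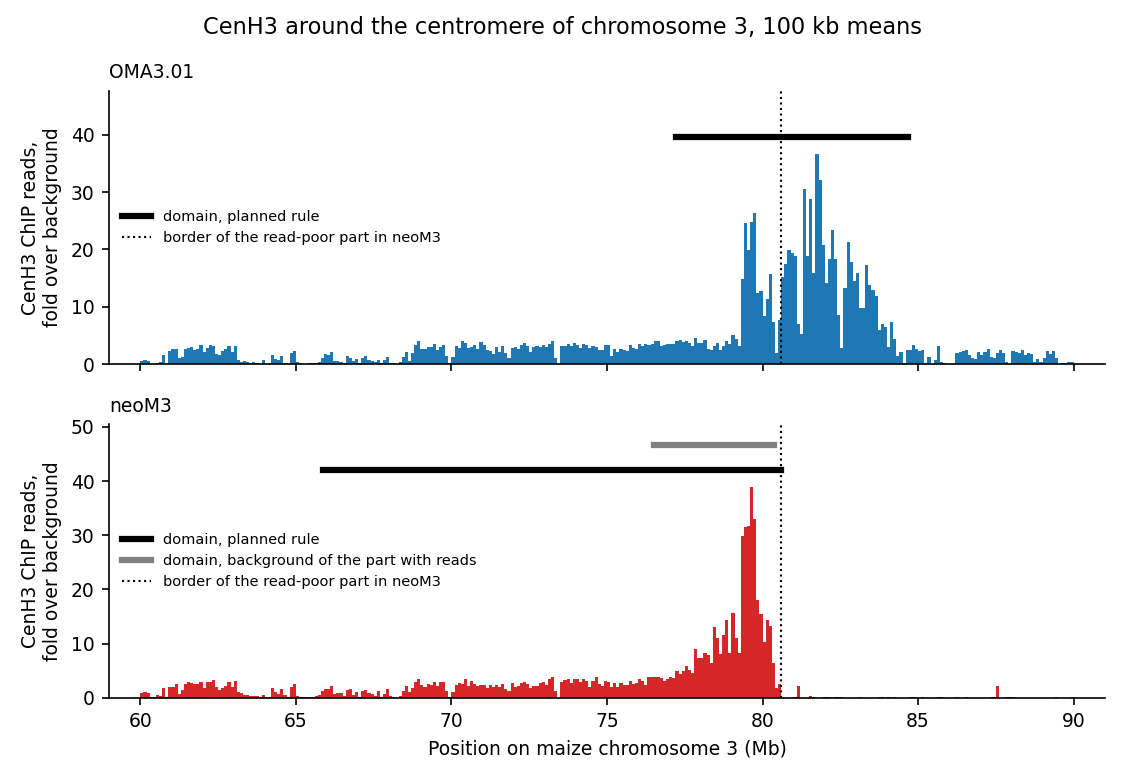
CenH3 ChIP-seq reads in 100 kb bins (vertical axis, fold over the background before the border of each library) against position on maize chromosome 3 in Mb, for OMA3.01 (top) and neoM3 (bottom), 1 library each; horizontal lines are the called domains and the dotted line is the border at 80.60 Mb. The OMA3.01 domain lies on both sides of the border. The figure covers 60 to 90 Mb, so the neoM3 pile at 165.5 Mb is outside it.

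The RNA-seq compared gene expression from chromosome 3 in the 2 lines. Genes after the 80.60 Mb border were on the whole far lower in neoM3, and genes before it were not. As deposited, 592 of 2216 tested genes were higher and 942 lower in neoM3 (limma on log2(FPKM + 1), Benjamini-Hochberg adjusted p threshold 0.05). Before the border 348 genes were higher and 58 lower of 673, with a median log2 difference of 0.75, and after it 244 were higher and 884 lower of 1543, with a median of -1.52. Genes before the neoM3 domain sat higher in neoM3 by 0.74 on the log2 scale. FPKM summed before the border was 360913 and 356697 in neoM3, and 206918 and 201248 in OMA3.01. After it the sums were 498314 and 489129 in neoM3, and 576840 and 581347 in OMA3.01. The read total behind FPKM is not given, so rises before the border as deposited cannot be told apart from an effect of scaling. Over the whole chromosome the sums were alike, 859227 and 845825 in neoM3 and 783758 and 782595 in OMA3.01. FPKM thus behaved nearly as a share of the chromosome, and a lower share after the border raises the share before it. The rises as deposited are therefore no evidence of higher expression before the border. Relative to the genes before the neoM3 domain, a scaling chosen after seeing the data, 182 genes were higher and 1191 lower. After the border 78 were then higher and 1060 lower, with a median of -2.27, and before it 104 were higher and 131 lower, with a median of 0.01. Centring on library medians instead gave 936 higher and 812 lower genes, and quantile normalization 845 higher and 611 lower. Without OMA3.01 replicate 1 the counts were 174 higher and 752 lower, and without OMA3.01 replicate 2 they were 167 higher and 718 lower.

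Detection followed the same line. After the border 39.7% of 2647 genes reached a mean of 1 FPKM in neoM3 and 58.9% in OMA3.01, and before it 52.3% and 55.9% of 1177 genes did. Read totals are not given in the sources used here, so lower depth of neoM3 may add to the gap on both sides of the border. Across genes, the most common ratio of OMA3.01 replicate 1 to neoM3 FPKM was 0.341 for neoM3 replicate 1 (11 genes, 7 at the next ratio). For neoM3 replicate 2 it was 0.38 (11 genes, 6 at the next). If these genes held equally few reads, 1 read gave more FPKM in neoM3, whose depth was then lower. A value of 0 and the 1 FPKM limit may therefore not mean the same in the 2 lines. After the border 462 genes were listed at 0 in both neoM3 libraries and at 1 FPKM or more in both OMA3.01 libraries, against 43 genes before it. Still, 1050 genes after the border reached 1 FPKM in neoM3, and the genes after the border made up 58.0 and 57.8% of the FPKM sum in its 2 libraries, against 73.6 and 74.3% in OMA3.01. The 10 highest genes of the chromosome held 56.9 and 51.5% of the sum in neoM3, and 47.8 and 47.7% in OMA3.01, so these shares may rest on few genes. In bins of 10 Mb, relative to the genes before the neoM3 domain, the median difference lay from 0 to 0.21 between 0 and 50 Mb. It was -0.35 at 50 to 60 Mb, -0.24 at 60 to 70 Mb and -0.57 at 70 to 80 Mb, and between -3.14 and -1.57 in every bin beyond.

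**Figure D3:**
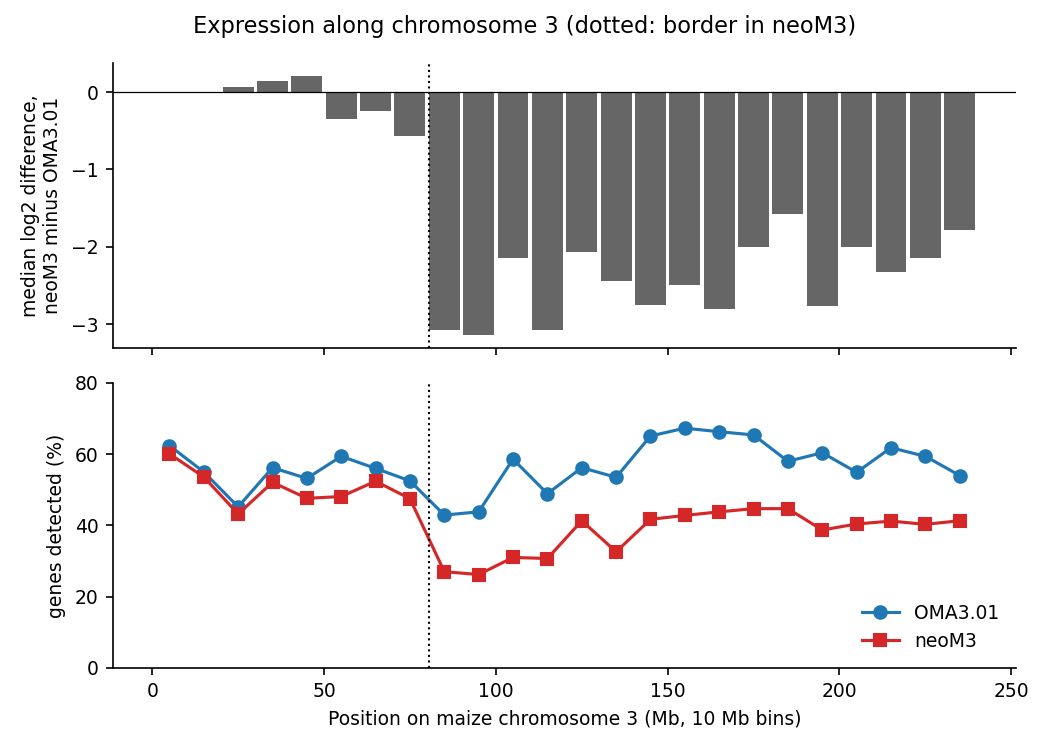
Median log2 difference in expression, neoM3 minus OMA3.01, relative to genes before the neoM3 domain (top), and percent of genes that reach a mean of 1 FPKM in each line (bottom), in 10 Mb bins of maize chromosome 3 (horizontal axis, Mb), 2 RNA-seq libraries per line. Bins beyond the border at 80.60 Mb have medians between -3.14 and -1.57.

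Genes under the CenH3 domains were compared to ask whether expression differs where a region carries CenH3 in one line and not, or less, in the other. Most of the neoM3 domain is not such a region. In 1 Mb bins from 66 to 77 Mb, CenH3 over background in neoM3 was 0.805 to 1.22 times that in OMA3.01. Of the 45 genes tested in this domain, 36 lie before 77 Mb, so most of the list tests no clear gain of CenH3. Of 76 genes listed inside the neoM3 domain by the planned rule, 45 were tested, 41 reached 1 FPKM in neoM3 and 45 in OMA3.01. As deposited, 15 rose and 14 fell over all genes tested, and the same numbers adjusted over the list alone. These counts depended on the scaling: 25 rose and 11 fell with centring on library medians. Fewer genes passed when either OMA3.01 library was left out, although the median log2 difference moved little (0.33 without replicate 1, 0.26 without replicate 2). With all 4 libraries the 45 genes had a median log2 difference of 0.36 and a mean of -0.48. limma camera, with a preset correlation, placed them above the other genes of the chromosome without passing the threshold (adjusted p = 0.15 over 3 lists, and 0.77 with an estimated correlation). fry, which asks whether the list itself moved, gave a fall, as the mean did, that was under 0.05 with no adjustment over the lists, but not at a mean of 5 FPKM, with the domain set at 10 times background or without either neoM3 library. It gave a rise with centring on library medians and with quantile normalization, where the mean was 0.23 and 0.41. Most of the other genes of the chromosome lie after the border. Set against genes before the border alone and relative to genes before the neoM3 domain, a setting chosen after seeing the data, 4 rose and 18 fell over all genes tested, and 4 and 19 adjusted over the list alone. Their median was then -0.38 against 0.04 for the other genes before the border (limma camera, adjusted p = 9.6e-05 over 3 lists). With an estimated correlation the list no longer passed (limma camera, adjusted p = 0.14). Without OMA3.01 replicate 1 no gene before the border passed over all genes tested (0 of 673 by limma, with 206 at p under 0.05 before adjustment), and 15 genes of the list fell adjusted over the list alone, with a median of -0.37. Without OMA3.01 replicate 2 none passed either (198 at p under 0.05 before adjustment), and 16 fell over the list alone, with a median of -0.52. With all 4 libraries 72 rose and 108 fell of these 673 genes, 276 of them at p under 0.05 before adjustment. In this fit the 88 genes from 50 Mb to the start of the domain had a median of -0.17, and 11 of them rose and 17 fell, while the 17 genes of the last 5 Mb before the domain had a median of 0.20.

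The narrower neoM3 domain, by the background of the part with reads, listed 14 genes and 9 were tested. As deposited 2 rose and 3 fell, with a median of -0.12, and camera placed the list above the other genes without passing. Among genes before the border alone 0 rose and 4 fell by limma, and the median was -0.86 (limma camera, adjusted p = 0.042 over 3 lists, and 0.22 with an estimated correlation). The OMA3.01 domain listed 29 genes and 13 were tested. As deposited 1 rose and 6 fell, over all genes tested and over the list alone, with a median of -0.96 and a mean of -1.58 (limma camera, adjusted p = 0.68). The counts were 5 and 5 with centring on library medians, with a median of -0.25, 4 and 5 with quantile normalization, 4 and 6 without neoM3 replicate 1, 1 and 3 without OMA3.01 replicate 1, and 0 and 3 without OMA3.01 replicate 2. Its 5 tested genes after the border had a median of -3.83 and 4 of them fell, while its 8 tested genes before the border had a median of 0.19, with 1 that rose and 2 that fell. The 5 Mb on either side of the neoM3 domain held 22 tested genes, of which 11 rose and 5 fell. Without OMA3.01 replicate 1 these counts were 3 and 4, and without OMA3.01 replicate 2 they were 4 and 3. Relative to the genes before the neoM3 domain 4 rose and 5 fell, with a median of -0.02, and among genes before the border alone 2 rose and 1 fell of 17. As deposited their median was 0.72 and their mean -0.54 (limma camera upward, adjusted p = 0.069 over 3 lists, and 0.77 with an estimated correlation). The 17 genes of the flank before the domain had a median of 0.95, and the 5 genes of the flank after it a median of -3.83.

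The files give gene IDs and do not pair them with gene names, so 4 genes of the fixed lists are named by ID. GRMZM2G157912, at 214726316 to 214729573, was among the 10 genes with the largest rise in neoM3 although it lies after the border, with 263 ± 39.5 FPKM in neoM3 and 18.3 ± 8.64 in OMA3.01 (SD, n = 2 each). Its log2 difference was 3.84 ± 0.40 (SE, limma adjusted p = 0.0054). After the border, 78 genes were higher in neoM3 relative to the genes before the neoM3 domain. CenH3 library reads within 50 kb of these genes were at a median of 0.085 of the OMA3.01 level, and 4 genes reached 0.5. The source of the GRMZM2G157912 transcripts in neoM3 was not tested. GRMZM2G177242, at 15061319 to 15062756 before the border, had 98.2 ± 33.1 FPKM in neoM3 and 9.46 ± 2.07 in OMA3.01, a log2 difference of 3.22 ± 0.33 (SE, limma adjusted p = 0.0052). GRMZM2G037644, at 209137271 to 209139596, stood for the 10 genes with the largest fall, which all lay after the border. It was listed at 0 in both neoM3 libraries, and at 1075 and 1066 FPKM in those of OMA3.01. GRMZM2G701576, at 79113161 to 79114807 inside both CenH3 domains, had 131 ± 30.1 FPKM in neoM3 and 379 ± 14.7 in OMA3.01, a log2 difference of -1.55 ± 0.20 (SE, limma adjusted p = 0.0087), and -2.29 relative to the genes before the neoM3 domain. Without OMA3.01 replicate 1 or 2, the adjusted p of GRMZM2G177242 was 0.08 and 0.072, and that of GRMZM2G701576 was 0.11 in both cases. Of the 10 genes with the highest mean inside the neoM3 domain, 4 fell and 5 rose as deposited, and in the fit of the genes before the border alone 5 fell and 0 rose.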

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

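The settings named here as added were chosen after the data were seen, and the others were planned. A domain that overlapped the planned one was found in every line and setting except OMA5.60 at 10 times background, where only a short pile was left, but the borders moved. The size did not hold. The mean over 9 lines was 5.94 Mb as planned, and 11.05 Mb at 3 times background, 3.81 at 10 times, 3.58 with merging up to 100 kb, 7.49 with merging up to 1 Mb, 8.79 without smoothing, 7.38 with the median background and 4.51 as enriched length. The added settings gave 4.73 (neoM3 background of the part with reads), 3.59 (25% of peak height) and 3.69 (pericentromeric background). Of the sizes of single lines, 75 moved and 17 did not, 8 of these under a setting that alters neoM3 alone and 2 in OMA8.05 with its own replicate left out. The relation of size to length turned from -0.06 to 0.36 at 3 times background, 0.17 with merging up to 100 kb, 0.34 without smoothing, 0.65 with the median background (exact permutation p = 0.088) and 0.44 at 25% of peak height (exact permutation p = 0.27). Without OMA1.36 and OMA10.26 the last was 0.84 (exact permutation p = 0.025), the only p under 0.05 among the settings, and the cause was not tested. The length shared by the neoM3 and OMA3.01 domains was 3.37 Mb, and in the order of the settings above 12.04, 1.24, 0.06, 4.91, 8.90 and 8.59, then 3.13, 1.04 and 1.04 under the added ones.

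Of the genes tested, 592 rose and 942 fell as deposited. The number that rose was 936 with centring on library medians, 182 with the added centring on genes before the neoM3 domain, 392 at a mean of 50 FPKM (added, fewer genes tested) and 167 to 593 when 1 library was left out. The number that fell was 611 with quantile normalization, 385 at a mean of 50 FPKM and 718 to 1013 when 1 library was left out. The median after the border minus that before it kept its sign throughout: -2.27 as planned, -2.67 with a pseudocount of 0.1, -2.20 without a filter, -2.14 at 5 FPKM, -1.50 with quantile normalization, -1.79 at 50 FPKM and -2.35 to -2.29 when 1 library was left out. The neoM3 domain list lay above the other genes (0.36) in all planned settings and below them in the added fits of genes before the border alone. These gave -0.38, -0.40 at 50 FPKM, -0.38 with an estimated correlation (limma camera, adjusted p = 0.14), -0.86 for the narrower domain (limma camera, adjusted p = 0.042, and 0.22 with an estimated correlation), and -0.37, -0.41, -0.47 and -0.52 when 1 library was left out; the genes it is compared with differ by construction. The OMA3.01 domain list (-0.96) was placed above the other genes by camera when an OMA3.01 library was left out (-1.08 and -0.63, limma camera, adjusted p = 0.83 and 0.94), and passed at -0.56 among genes before the border alone (limma camera, adjusted p = 0.042, and 0.22 with an estimated correlation), but not without neoM3 replicate 1 (-0.26) or OMA3.01 replicate 1 (-0.41). The flank list (0.72) passed before adjustment over the 3 lists and not after it (limma camera, adjusted p = 0.069). It failed before adjustment too with centring on library medians (1.43), quantile normalization (1.29), an estimated correlation (0.72), among genes before the border alone (0.20, with either correlation), and without neoM3 replicate 2 (0.52) or OMA3.01 replicate 1 (0.78). It passed after adjustment without neoM3 replicate 1 (1.01) and with the added centring, where its median was -0.02 and the other genes, most of them after the border, lay at -1.31. fry, for the neoM3 domain and flank lists, turned from a fall to a rise with centring on library medians and quantile normalization, and for the flank list also without neoM3 replicate 1, at 50 FPKM and among genes before the border alone. Its fall for the neoM3 domain list was under 0.05 as planned, but not at 5 FPKM, with the domain set at 10 times background, without either neoM3 library or, of the added settings, at 50 FPKM. For these changes the cause was not tested.

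Replicate numbers of the 2 lines showed no pairing (correlation of deviations 0.013, 2 pairs). With the number as a block 559 genes rose and 924 fell, and the fall by fry for the neoM3 domain list was not under 0.05. Among 673 genes before the border alone, 0 then rose and 0 fell (260 at p under 0.05 before adjustment). The neoM3 domain list was at -0.38 (limma camera, adjusted p = 0.00019, and 0.14 unblocked with an estimated correlation). Of the 4 genes printed by ID, 2 lost their call without either OMA3.01 library. Lists by words in gene descriptions were not run.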

Other observations

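Of the tests in this part, only that of gene windows outside the highest 5% for reads from oat genes was written before its result was seen, and its explanation was narrowed afterwards from oat reads in general to oat genes. All the others were chosen after the result was seen.

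The pile at 165.47 Mb of chromosome 3 was present in both lines, with 17196 reads in neoM3 and 22401 in OMA3.01, although it lies in the part that is read-poor in neoM3. Over the background before the border of each library, at 165.47 to 165.54 Mb, this was 208 times in neoM3 and 72.3 times in OMA3.01, so that the scaled pile was higher in neoM3. The neoM3 reads after the border numbered 37854 in total. In the RNA-seq the same gene had the highest FPKM in all 4 libraries, with 16.9 and 15.1% of the FPKM sum in neoM3 and 9.7 and 8.9% in OMA3.01.

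Reads and transcripts that remain in neoM3 after the border were weighed at the start, and loss of the chromosome part remains a hypothesis. Plants or cells that carry the whole chromosome as the whole source are argued against by the OMA3.01 peak after the border, seen in neoM3 at 0.803% (95% counting interval 0.737 to 0.874%) against 5.05% of the background there. Oat genes as the source of the thinly spread ChIP-seq reads are argued against by windows with a gene, which held 0.57 (0.53 to 0.62) times the reads of other windows after the OMA3.01 domain and 1.59 (1.44 to 1.77) times before the neoM3 domain. These values leave out the highest 5% of windows and cover 19.4% of the neoM3 reads after the OMA3.01 domain. In the highest windows 71.2% of the reads lay in gene windows, although gene windows were 19.3% of them against 21.1% of all windows there. Of all neoM3 reads after the OMA3.01 domain, 10 windows held 62.0%, and with no window left out the ratio was 5.59. Oat genes therefore stay open in the highest windows, and oat repeats were not tested. Retained pieces that reach 50 kb past the detected genes are argued against as the whole source of the transcripts. The median ratio of reads within 50 kb was 0.074 around 1049 genes detected in neoM3, though 46 of these reached 0.5. The reads were averaged over that stretch, so shorter pieces could not be seen. Whether these transcripts come from oat could not be told apart from maize copies elsewhere, since no oat library or sequence was analysed here.

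Lower expression of genes inside the neoM3 domain than of other genes before the border was weighed next, although the difference did not pass with an estimated correlation (limma camera, adjusted p = 0.14). Loss of the whole stretch within 50 kb of the 18 genes that fell is argued against by the CenH3 library reads there. These were at a median of 0.98 of the OMA3.01 level (lowest gene 0.52, highest 2.80). They follow CenH3 as well as DNA and are averaged over the stretch, so loss of a gene alone could not be seen. Low depth is argued against by the genes of at least 50 FPKM, whose median was -0.40. Gained CenH3 stays open: the 7 genes from 77 to 80 Mb, where CenH3 rose by a limit chosen after the data were seen, had a median of -0.86 (1.9% of random sets of other genes lay as low), and the 38 other domain genes -0.35 (0.36%), as low as 6.1% of the runs of 38 neighbouring genes before the domain, of which only 16 do not overlap. The parts did not differ detectably (permutation p = 0.65), and the median of the gained part is fragile: taken up to the border at 80.60 Mb, as was done first although CenH3 was lower in neoM3 next to the border, it held 9 genes at -0.25 (17% of random sets), against -0.39 for the other 36 (permutation p = 0.66; 4.9% of runs as low). Reads shared with copies after the border also stay open for the 18 genes, as no sequence was analysed here. A fall that begins before the domain stays open too. The 88 genes from 50 Mb on, a limit chosen from the bins, had a median of -0.17, against 0.06 for the 540 genes from 0 to 50 Mb (permutation p = 0.023). Domain genes did not differ detectably from these 88 (permutation p = 0.15). The 17 genes of the 5 Mb before the domain had 0.20, above the domain genes (permutation p = 0.0092).

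Domain sizes that differ between lines were weighed over 8 lines without neoM3. The 4 lines with an uneven background (interquartile range above 1.5 times the median outside the domain) kept 57.9% ± 19.3 (SD) of their span at 25% of peak height, and the 4 even lines 109.5% ± 28.9 (exact permutation p = 0.029, the smallest that 70 splits allow). Their planned sizes were 6.41 ± 1.68 and 3.28 ± 1.03 Mb (exact permutation p = 0.057), and those at 25% of peak height 3.52 ± 0.97 and 3.48 ± 0.91 Mb (exact permutation p = 1). The threshold at 25% of peak height rises with the peak over background, so lines with high peaks can lose span under it whatever their evenness. The share kept also has the planned span as its denominator. This comparison therefore cannot separate evenness of the background from peak height. Part of the spread in size may come from how background is set, and the limit of 1.5 was chosen with the sizes known. The biological explanation, that chromosomes differ in centromere size, stays open.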
